A study of Colpoda aspera with 2 samples.

How the data were processed

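Messenger RNA of the free-living soil ciliate Colpoda aspera was sequenced from living (vegetative) cultures and from cells induced to form resting cysts, with 1 library of each. Per the labels' protocols, cells grew for 3 days at 30 °C in sterile 1% Luria-Bertani medium in phosphate-buffered saline. Encystment was induced by spinning the cells down and rinsing them in saline, after which most cells became cysts within 24 h. The time at which the encysting cells were taken is not given in the sources used here. Per the labels' protocols, polyadenylated RNA was selected on oligo(dT) beads and made into strand-specific libraries for an Illumina HiSeq instrument. The protocol describes single-end reads of 52 nt for some libraries and paired-end reads of 101 nt for another, under codes that match neither sample, so the read layout of these 2 libraries is not known.

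The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled by library depth), with 3 decimals, for 49543 assembled transcripts in both libraries. FPKM divides a transcript's reads by its length and by the library's depth. It does not by itself equalise the sum over transcripts, and any factor applied per library changes that sum too. The sum was 1188102 in the living and 933749 in the encysting library. The submitters' processing notes name edgeR 3.20.9 with no role. The assembler, aligner, counting tool, filters and any scaling between libraries are not given in the sources used here. The table held no lengths, counts, gene names or descriptions, no reference was used, and 0 columns of other samples were present. Transcripts are therefore given by their identifiers, which the file does not pair with genes, and whether a transcript belongs to the ciliate or to another organism in the culture is not known. The gene lists fixed before the data were examined could not be applied. The identifiers have the form component, subcomponent (c) and sequence (seq), a form that older releases of the Trinity assembler write. They fell into 33326 components and 37166 subcomponents, of which 32220 held 1 sequence. Sequences of 1 subcomponent usually share stretches, and how reads that match several of them were counted is not given in the sources used here.

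Differences are encysting minus living on the log2(FPKM + 1) scale, which understates the change of low transcripts, over the 42866 transcripts with an FPKM of at least 1 in either library. A transcript was counted as higher or lower when this difference reached 1 in size, that is 2-fold. With 1 library per group there was no replicate spread, so no p-value was computed and every statement compares these 2 libraries only. Intervals are 95% bootstrap intervals over transcripts (1000 resamples). They describe how far a result moves when transcripts are resampled, and not the spread of single transcripts. Transcripts are not replicates, and for the class medians sequences of 1 subcomponent were resampled as if independent. The intervals include no variation between cultures. The trend with abundance used log2 ratios without a pseudocount, over the 42492 transcripts above 0 in both libraries, in 8 classes of the geometric mean FPKM, which treats both libraries alike. Named transcripts were the 2 with the largest positive and the 2 with the largest negative difference among those with an FPKM of at least 10 in the higher library, a rule set before the data were examined.

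The total read count per library is unknown. The low values show only what 1 read was worth in each library, which takes in depth and any scaling between libraries. Where whole reads are counted, the ratio between libraries of a low transcript takes only a few values. Of 20888 transcripts above 0 and under an FPKM of 3 in both libraries, 2583 had a ratio between 1.035 and 1.079, against 230 and 229 in the neighbouring windows of the same width. One read in the encysting library was thus worth 1.06 times the FPKM of one read in the living library (median in that window). The inverse, 0.943, would be the ratio of read depths only without a scaling between libraries. Neighbouring low values were spaced more widely in the living than in the encysting library. If values were rounded before scaling, this spacing points to a scaling between libraries, with a larger factor for the living library. That would put the ratio of depths below 0.943. The factors were not worked out, so the ratio of depths is not given. Ratios of 7 small whole numbers (1:1, 1:2, 1:3, 2:3 and their inverses, each within 0.03 on the log2 scale) took in 43.5% of transcripts with a maximum FPKM under 1, 33.1% from 1 to 3 and 17.7% from 3 to 10. The same windows shifted by 0.2 took in 7.08%, 7.53% and 8.48%. From 10 to 30 the shares were 10.3% and 9.51%. Many values under an FPKM of 3, and some up to 10, therefore rested on few reads.

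Alternatives were pseudocounts of 0.1 and 10, no filter and a filter at an FPKM of 10, thresholds of 4-fold and 8-fold, and centring on library medians or on a trimmed mean of log ratios (30% trimmed from each end of the ratios and 5% of the means). Added after seeing the data were a trimmed mean over transcripts with an FPKM of 10 or more in both libraries, scaling to the same summed FPKM, values summed per subcomponent, and sequences alone in their subcomponent. On simulated data with 200 of 49543 transcripts changed 4-fold, the counting recovered 100% of them with 0 false calls, and a simulated read value of 0.15 (log2) was found as 0.15. That simulation had a small spread, and all changed transcripts had an FPKM of at least 10 in living cells, so recovery was near certain. It checks the counting code and does not measure error for low transcripts or between cultures. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.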

Results

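The transcriptomes of living and encysting Colpoda aspera cells were compared with 1 library per stage, to find which transcripts differ in level between the 2 states. Of 49543 assembled transcripts, 33786 had an FPKM of at least 1 in living cells and 36866 in encysting cells. An FPKM of at least 10 was reached by 9456 and 9063 transcripts, and an FPKM of at least 1000 by 187 and 140. In living cells 4485 transcripts were listed at 0, in encysting cells 3600, and 1034 in both. One read in the encysting library was worth 1.06 times the FPKM of one read in the living library, as read from the ratios of low transcripts. That value includes any scaling between libraries. The scaling was not worked out, so no relative read depth is given, and the absolute depth is not known. There were no replicates, so none of the differences could be set against a spread between cultures.

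**Figure D1:**
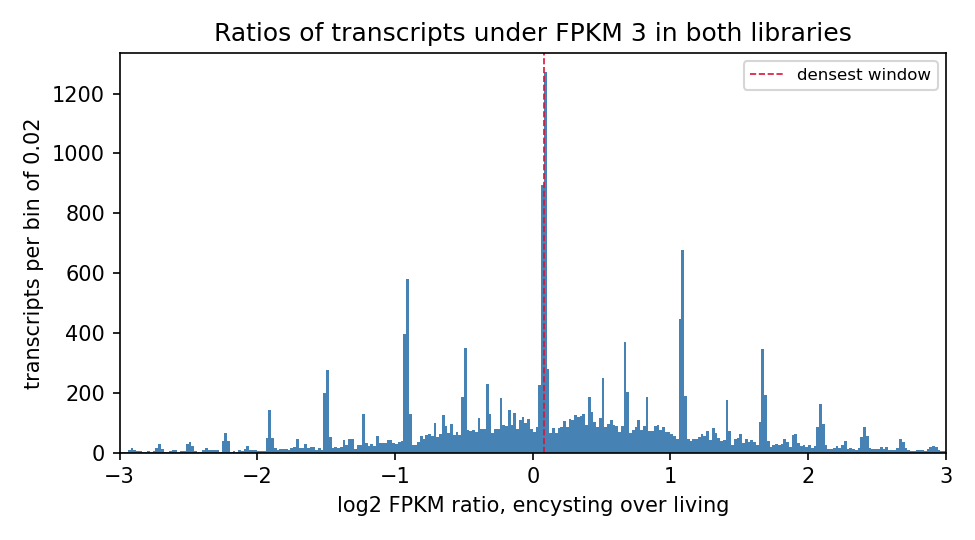
Number of transcripts (y axis, bins of 0.02) by the log2 ratio of encysting to living FPKM (x axis), for the 20888 transcripts above 0 and under an FPKM of 3 in both libraries. The ratios pile up at a few values, with 2583 transcripts in the window around the dashed line, which is where equal numbers of reads fall.

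The mRNA pools of both stages shared their broad ranking but differed at many transcripts. Among 42866 transcripts with an FPKM of at least 1 in either library, 6872 (16.0%) were at least 2-fold higher in encysting cells and 6415 (14.97%) at least 2-fold lower. The other 29579 (69.0%) lay within 2-fold. At least 4-fold differences numbered 1843 higher and 1661 lower, and at least 8-fold differences 392 higher and 255 lower. The median difference was 0.05 (log2), with an interquartile range from -0.58 to 0.68. Across transcripts, Pearson's r of log2(FPKM + 1) was 0.825 and Spearman's rho of FPKM was 0.639. Transcripts are not independent replicates, and no p-value was attached to these correlations. Low transcripts made up most of the counts: 5405 of the higher transcripts (78.7%) and 3894 of the lower ones (60.7%) stayed under an FPKM of 10 in both libraries, a range in which part of the values rested on few reads.

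Among the better-measured transcripts the balance leaned the other way. Of 10996 transcripts with an FPKM of at least 10 in either library, 1467 were at least 2-fold higher in encysting cells and 2521 at least 2-fold lower, with a median difference of -0.22 (log2). This split depended on how the libraries were put on a common scale. As deposited, 36.8% of the changed transcripts in this range were higher in encysting cells. After scaling both libraries to the same summed FPKM, a setting chosen after seeing the data, 56.9% were (2197 higher and 1662 lower). Centring on the trimmed mean over transcripts with an FPKM of at least 10 in both libraries gave 49.0% (1880 and 1956). This setting was also chosen after seeing the data. The centrings planned before the data were examined moved it the other way, to 30.3% on library medians (1269 and 2923) and 32.7% on the trimmed mean over all transcripts (1344 and 2772). Over all 42866 transcripts the higher share was 51.7% as deposited, 43.8% on library medians and 46.9% on the trimmed mean over all transcripts. It was 65.4% on the trimmed mean over transcripts at 10 or more in both libraries. With equal sums it was 73.2% (11169 higher and 4098 lower). Equal sums moved the median of all transcripts by 0.35 on the log2 scale. Neighbouring low values were spaced more widely in the living than in the encysting library, a reading separate from the value of a read given above. If values were rounded before scaling, this spacing points to a factor per library already in the deposited values, larger for the living library. The factors were not worked out. Equal sums work against such a factor. The table alone does not say which scale is right, so whether more transcripts were higher or lower in encysting cells is not settled by these libraries.

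**Figure D2:**
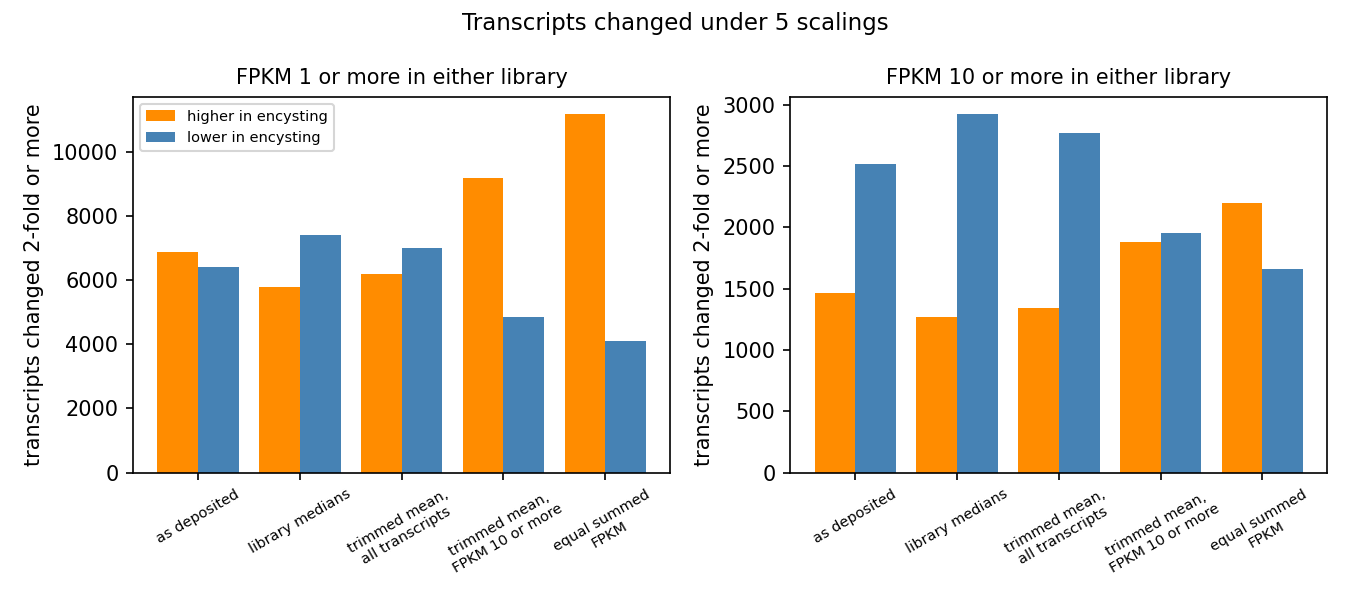
Number of transcripts at least 2-fold higher (orange) or lower (blue) in encysting cells (y axes, from 0) under 5 scalings of the libraries (x axes), for transcripts with an FPKM of at least 1 (left) or 10 (right) in either library. On the right, more transcripts are lower as deposited (2521 against 1467) and more are higher with equal summed FPKM (2197 against 1662).

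The class medians of the change were graded by abundance, being lower in encysting relative to living cells in the more abundant classes, while single transcripts scattered widely within each class. Among 149 transcripts with a geometric mean FPKM of 1000 or more, the median log2 ratio of encysting to living was -0.63 (95% bootstrap interval -0.70 to -0.57), a ratio of 0.648. It was -0.54 (-0.65 to -0.44) for 377 transcripts from 300 to 1000, -0.48 (-0.57 to -0.40) for 993 from 100 to 300, and -0.27 (-0.31 to -0.23) for 2655 from 30 to 100. It was -0.12 (-0.15 to -0.09) for 4797 transcripts from 10 to 30 and 0.04 (0.02 to 0.05) for 9133 from 3 to 10. In the class of 1 to 3 it was 0.10, and below 1 it was 0.23, both in the range of few reads. The median of the top class minus that of the class from 3 to 10 was -0.67 (-0.74 to -0.61). The SD of the log2 ratio over transcripts within a class was 0.67 in the top class and between 1.02 and 1.46 in the others, as large as or larger than this shift of the medians. Across the 4174 transcripts with a geometric mean of 30 or more, Spearman's rho of the ratio with abundance was -0.085. The share of transcripts at least 2-fold lower in encysting cells was 15.8% from 3 to 10, 26.3% from 300 to 1000 and 11.4% in the top class, so it did not follow the medians throughout. A common factor per library shifts all classes alike, so the difference between class medians does not depend on the scaling, although the sign within a class can: with equal sums the medians were -0.28 in the top class and 0.39 in the class from 3 to 10. The spread of log2 FPKM over transcripts above 0 in both libraries was smaller in encysting cells (SD 2.24) than in living cells (SD 2.44). On the same transcripts this is another view of the grading and not separate evidence for it.

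**Figure D3:**
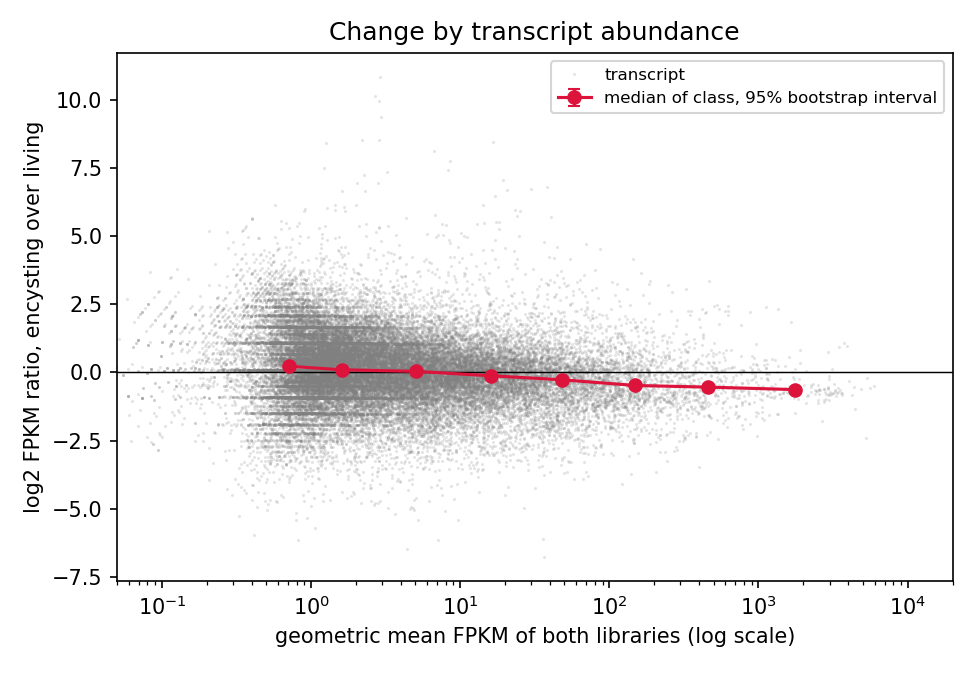
Log2 ratio of encysting to living FPKM (y axis) against the geometric mean FPKM of both libraries (x axis, log scale). Grey points are the transcripts above 0 in both libraries within the plotted range and red points the class medians with 95% bootstrap intervals over transcripts, which go from 0.23 below an FPKM of 1 to -0.63 at 1000 or more.

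The lists of most abundant transcripts overlapped in part between the stages. Of the 10 most abundant in each library, 5 were in both lists, of the 100 most abundant, 79, and of the 1000 most abundant, 707. The most abundant transcript of living cells ranked 38 in encysting cells, and that of encysting cells ranked 59 in living cells. The 100 most abundant made up 27.8% of the summed FPKM in living cells and 24.4% in encysting cells, and the highest value was 12120 in living and 5469 in encysting cells. Of the 100 most abundant in living cells, 94 had a lower FPKM in encysting cells, 17 of them by at least 2-fold, and 1 was at least 2-fold higher. Ranking by the living library favours such lower values, so the mirrored list was also read. Of the 100 most abundant in encysting cells, 27 were higher there than in living cells, 11 by at least 2-fold, and 9 were at least 2-fold lower. Their median difference was -0.57 (log2). The counts of higher and lower transcripts, this median and the highest values depend on the scaling. They are given as deposited and were not repeated under another scaling.

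The largest differences were between transcripts at or near 0 in one stage and abundant in the other. The transcript comp16310_c0_seq1 was listed at 0 in living cells and had an FPKM of 353 in encysting cells, the largest positive difference. It was the only sequence of its component. The next, comp22170_c0_seq2, was also listed at 0 in living cells and had an FPKM of 203 in encysting cells. The 3 sequences of its subcomponent together had an FPKM of 6.20 in living and 560.2 in encysting cells, so the subcomponent was low but not at 0 in living cells. In the other direction, comp5862_c0_seq1 had an FPKM of 378 in living and 3.51 in encysting cells, a ratio of 108. The next, comp5862_c1_seq1, had 295 and 4.32, a ratio of 68.3, and is the only other sequence of the same component. The table does not say which proteins these transcripts encode.

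Transcripts listed at 0 in one stage were mostly low in the other. There were 82 transcripts listed at 0 in living cells with an FPKM of at least 10 in encysting cells (median 11.9, highest 353), and 41 listed at 0 in encysting cells with at least 10 in living cells (median 10.97, highest 30.6). For 62 of the 82 and 33 of the 41, the whole subcomponent was listed at 0. At a floor of 100, 3 transcripts were listed at 0 in living cells and 0 in encysting cells. An exact 0 here does not show that the transcript was absent, since the depth, the counting tool and any filter are unknown.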

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

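Counts of changed transcripts depended on the fold threshold, the pseudocount, the filter at an FPKM of 10 and the scaling. At 2-fold, 6872 transcripts were higher and 6415 lower in encysting cells. Thresholds of 4-fold and 8-fold gave 1843 higher and 1661 lower, and 392 and 255. A pseudocount of 0.1 gave 10629 and 8500, and one of 10 gave 768 and 1436. Dropping the filter could not change either count, because at a pseudocount of 1 a transcript under an FPKM of 1 in both libraries cannot reach 2-fold. A filter at an FPKM of 10 left 1467 and 2521. Fewer transcripts tested lowers both counts. The turn of the balance towards lower goes with the grading by abundance, since the filter removes low transcripts. By ratios without a pseudocount, 24.8% were at least 2-fold higher and 12.7% lower at a geometric mean FPKM of 1 to 3. From 30 to 100 the shares were 10.3% and 23.8%. The cause of that grading is not settled. Equal summed FPKM, added after seeing the data, gave 11169 and 4098. Centring on library medians (5783 and 7416) or on the trimmed mean over all transcripts (6188 and 6992) stayed within 1.5 times but turned the balance towards lower. The median change of 0.05 (log2) was 0.073 and 0.014 with pseudocounts of 0.1 and 10, 0.045 without a filter, -0.22 with the filter at 10, -0.077 on library medians, -0.027 on the trimmed mean over all transcripts, 0.26 with the trimmed mean over transcripts at an FPKM of 10 or more, and 0.40 with equal sums. The 82 transcripts listed at 0 in living cells became 3047 at a floor of 1 and 3 at a floor of 100, and the 41 listed at 0 in encysting cells became 2285 and 0. The 10 most abundant transcripts held 5.50% of the summed FPKM in living and 4.86% in encysting cells, and the 1000 most abundant 64.3% and 59.6%. The correlation of 0.825 was 0.644 with a pseudocount of 0.1, 0.840 without a filter and 0.748 with the filter at 10. Summing per subcomponent gave 5802 higher and 5416 lower. The named transcripts kept their direction under both pseudocounts and both planned centrings. The planned gene list medians were not run, because the table pairs no identifier with a name. No paired analysis was possible because each stage has 1 library. No replicate could be left out, and absolute depth, which limits all low values, is unknown.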

Other observations

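All tests in this part were chosen after the results they bear on had been seen. The 100 transcripts with the largest positive differences, among 10996 with an FPKM of at least 10 in either library, came from only 71 subcomponents. Random sets of 100 matched on mean expression came from a median of 100 subcomponents, and from 95 in the lowest of 10000 sets. One subcomponent gave 12 of the 100, and 8 subcomponents together gave 37. The 100 largest negative differences came from 94 subcomponents, against a median of 99 and a lowest value of 93 in the random sets, near the bottom of the random range. When FPKM was summed per subcomponent first, the 100 subcomponents with the largest positive differences came from 94 components, and those with the largest negative differences also from 94. The lowest values of 10000 matched random sets were 97 and 96. Of the 100 transcripts, 46 of the positive and 27 of the negative set came from subcomponents with several sequences. The random sets were not matched on this. Sequences of 1 subcomponent can share reads and so change together, which alone can lower the number of subcomponents below that of random sets. These counts therefore describe the assembly as well as the genes, and the contrast between the 2 directions was not tested.

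Where a subcomponent held several sequences, the leading one often differed between the stages, but large exchanges were rare. Of 1691 subcomponents with 2 or more sequences and a summed FPKM of at least 10 in both libraries, 408 (24.1%) had a different leading sequence in the 2 libraries. In 3 of them a sequence gained at least 50 percentage points of the subcomponent's FPKM, and in all 3 the total stayed within 2-fold. In 59 (3.49%), 1 sequence was at least 2-fold higher and another at least 2-fold lower in encysting cells. Without replicates, the number of such exchanges between cultures of the same stage is not known.

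The grading of the class medians by abundance is the pattern most open to follow-up. One candidate is an equal background added to every transcript of the encysting library, after a common loss set by the top class. To give the class from 30 to 100 by itself, it would need an FPKM of 9.62 (95% bootstrap interval 8.56 to 10.6). In the encysting library 79.7% of transcripts lay below the lower bound, which argues against a background of that size. A smaller background that adds to the grading was not tested. Division of reads between sequences of 1 subcomponent is argued against by the sequences alone in their subcomponent. In these the difference between the top class and the class from 3 to 10 was -0.70 (-0.78 to -0.64). This set could still share reads between subcomponents, since 3195 components held 2 or more, so sharing of that kind stays open. Few reads behind scarce transcripts cannot be the whole cause, since the top class still lay below the class from 30 to 100 by a difference of -0.36 (-0.44 to -0.29). A change of the mRNA pool with encystment may remain as a hypothesis, but a difference in fragment length, read layout or RNA quality between the 2 libraries, and variation between cultures, stay open and were not tested, since the table gives no transcript lengths and each stage has 1 library.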
